A study of Mus musculus with 6 samples.

How the data were processed

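The series holds 6 one-colour Affymetrix arrays of RNA from B16-F1 cells, 2 for each of 3 stable shRNA lines, and its description gives the 2 arrays of a line as independent biological replicates. Groups and replicate numbers were taken from the sample labels. The deposited values are signal intensities on a linear scale, 1 per probe set, made with MAS5 per the submitters' processing notes, and the version of that software is not given in the sources used here. The deposited intensities had a 2% trimmed mean of 150.0 on all 6 arrays, so each array had been scaled to a common level before deposit, and this scaling removes any change in total signal between the lines. The arrays carried 45101 probe sets, of which 64 were control probe sets and were left out of all tests. Of the 45037 others, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Names were taken only from probe sets with 1 symbol, of which 34741 matched a current gene record by its Entrez identifier, and 0 symbols were updated by that match. A genome build is not given in the sources used here, and gene positions from a reference gene table served only to order the genes around Cdk8.

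Signals were analysed as log2(signal + 16), so fold changes are on that scale and understate the change of dim probe sets. Probe sets were tested when their mean signal over the 6 arrays was at or above the 40th percentile of all probe sets, 10.4 signal units, which left 27025 probe sets, 22703 of them with 1 symbol, for 12088 genes. All arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a variance trend) with 3 group means and 3 residual degrees of freedom, to which the moderation added 4.90 prior degrees of freedom. The contrasts were macroH2A1 shRNA minus control, macroH2A2 shRNA minus control, the mean of both minus control, and macroH2A2 shRNA minus macroH2A1 shRNA. The threshold was a two-sided Benjamini-Hochberg adjusted p under 0.05.

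The labels give the same replicate numbers in each line, without saying that a number marks a shared batch. The files were therefore checked once. The replicate 1 minus replicate 2 differences of the lines correlated across tested probe sets with 0.576, 0.372 and 0.415 for the 3 pairs of lines. The median difference over 24 poly-A spike-in probe sets, which do not measure cellular RNA, was 0.53 in the control line, 0.42 in the macroH2A1 shRNA line and 0.17 in the macroH2A2 shRNA line. The 18 hybridisation control probe sets differed by 0.053, 0.37 and 0.12, so they did not follow the spike-ins in the control line. The 3 probe sets for 18S rRNA differed by 0.59, 0.52 and 0.54. The first principal component, 49.8% of the variance, placed the replicate 1 arrays at -45.1, -26.4 and -11.5 and the replicate 2 arrays at 21.9, 32.8 and 28.2. The replicate sets were treated on this ground as a batch seen in the data. A fit with the replicate number as a block has 2 residual degrees of freedom and 9.09 prior degrees of freedom, and its values and those within each set stand beside the results they change.

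The genes named were chosen by a rule. It takes Macroh2a1, Macroh2a2 and Cdk8 in every comparison, and per comparison the 10 largest rises and 10 largest falls among probe sets past the threshold whose groups of arrays do not overlap. Where fewer pass, those with the smallest p among the rest with non-overlapping groups are added until 5 are named in each direction, as values. For a gene list it takes up to 4 members with the smallest p. In gene lists, and among probe sets past the threshold, a gene with several probe sets was represented by the brightest. A gene added for its small p was represented by its probe set with the smallest p among those with non-overlapping groups. Without the block this held for all genes named per comparison, since 0 probe sets passed. In total 29 gene lists with 885 symbols were fixed, of which 774 symbols matched the array annotation and 111 did not. They cover macroH2A and H2A variant genes, core histones, chromatin regulators, the Mediator kinase module, cell cycle and p53 groups, MAP kinase and beta-catenin targets, melanocyte, adhesion, matrix, secreted, interferon, antigen presentation, metabolic and stress groups, imprinted genes, homeobox and other Polycomb targets, and markers of leukocytes, fibroblasts, keratinocytes and endothelial cells. Lists with at least 5 tested members, 27 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a contrast. Camera with an estimated correlation called 0 lists in each of the 4 contrasts. The fry test, which asks whether the members of a list move one way on balance, also called 0 lists in each, with smallest adjusted p values of 0.0773, 0.366, 0.102 and 0.203. Its mixed form, which lets members move either way, gave smallest adjusted p values of 0.00926, 0.0440, 0.0105 and 0.0587. These came from the Mediator kinase module, which holds Cdk8, or from the variant genes, which include Macroh2a1. For macroH2A1 shRNA the mixed fry adjusted p was also under 0.05 for ribosomal proteins (0.0109), interferon-stimulated genes (0.0212) and PARP and NAD genes (0.0212). For the mean of both lines the same lists had 0.0118, 0.0150 and 0.0150.

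The procedure was tested on simulated data for macroH2A1 shRNA minus control with 27025 probe sets, 200 of them changed, in 20 draws. Without the block it found 7.45% of probe sets changed by 1 on the log2 scale and 69.0% of those changed by 2, and 0.0654% of its calls were false. With the block it found 56.0% and 99.2%, and 5.02% of its calls were false. The simulated data were built from the blocked fit, with an additive effect of the replicate set and the spread of that fit. These rates therefore do not test whether the blocked model holds for the arrays. A shift of 0.5 in the 30 interferon-stimulated genes, over 12088 genes, was called in 20 of 20 draws with the preset correlation and in 8 of 20 with an estimated one. The simulated errors were independent between genes, while the correlation estimated for this list in the data was 0.217. For the correlation of fold changes between the lines, unchanged groups were simulated against the same controls in 20 draws.

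Alternatives were a pseudocount of 1 or 64, quantile normalization, centring of the arrays, no filter or a 60th percentile filter, no variance trend, only the groups compared, the replicate block, an adjusted p under 0.10, a fold change of at least 2, the mean of a gene's probe sets, an estimated inter-gene correlation, and leaving out each array in turn. These, the groups, the tests, the lists and the rule for named genes were chosen before the data were examined. The settings of the blocked fit, and for gene lists the block with an estimated correlation, the centring and the pseudocount of 1, were chosen after seeing the data. The number of arrays limits the precision.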

Results

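Gene expression was measured in B16-F1 cells, a mouse melanoma line of the C57BL/6J strain, that stably carried a lentiviral short hairpin RNA (shRNA). The hairpin was directed against macroH2A1, against macroH2A2 or, in the control line, against GFP. MacroH2A proteins are histone H2A variants that carry a large additional macro domain. Each of the 3 lines was represented by 2 biological replicates, so that 6 one-colour arrays with 45101 probe sets each entered the comparisons, and this number limits the precision of every value. The 2% trimmed mean signal was 150.0 on all 6 arrays, while the median signal lay between 15.1 and 24.6. Pairs of arrays correlated with r between 0.972 and 0.989 across probe sets, and no array held the values of another. The replicate 1 arrays differed from the replicate 2 arrays in a way that the 3 lines shared in part. These differences correlated between lines with r from 0.372 to 0.576. Values from a fit with the replicate set as a block, and values within each set, therefore stand beside the results whose call they change.

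The targeted genes were examined first. Macroh2a1 (H2afy in older annotation) had a signal of 1238 ± 35.1 in the control line, 381.7 ± 88.5 in the macroH2A1 shRNA line and 1221 ± 71.2 in the macroH2A2 shRNA line (mean ± SD, n = 2 arrays each). The macroH2A1 shRNA arrays read 444.2 and 319.1 against 1212.7 and 1262.4 in the control arrays, a 3.19-fold lower level. The log2 fold change was -1.67 (SE 0.17), with -1.42 in replicate set 1 and -1.93 in set 2. As a gene named beforehand, Macroh2a1 had an unadjusted limma p of 1.04e-05 without the block. Adjusted over all tested probe sets, its limma p was 0.123 without the block and 0.00120 with it. By that adjustment it passed the threshold only with the block. Over 11 further settings of the blocked fit its adjusted p lay between 1.01e-06 and 0.0807, and was under 0.05 in 10, the exception being the fit without the signal filter. In the macroH2A2 shRNA line the log2 fold change of Macroh2a1 was -0.02 (SE 0.17).

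Macroh2a2 (H2afy2 in older annotation) was dim on every array. Its signals were 6.1 and 7.5 in the control line, 3.5 and 2.0 in the macroH2A1 shRNA line and 11.9 and 8.3 in the macroH2A2 shRNA line, and its mean lay below the filter of 10.4 signal units. The log2 fold change in the macroH2A2 shRNA line was 0.19 (SE 0.16), with a limma adjusted p of 1 in a fit without the filter. At this signal a knockdown of Macroh2a2 was not detectable, so the arrays do not check that label, and directions drawn from this line rest on the label alone.

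Cdk8, the kinase of the Mediator complex that the published work on these lines followed up, was higher in both macroH2A shRNA lines. Its signal was 234.9 ± 15.4 in the control line, 606.6 ± 105 in the macroH2A1 shRNA line and 616.7 ± 73.8 in the macroH2A2 shRNA line (mean ± SD, n = 2 each). The control arrays read 245.8 and 224.0, and the other arrays 532.5, 680.7, 564.5 and 668.8. The log2 fold changes were 1.30 (SE 0.17) and 1.33 (SE 0.17), a 2.47-fold and a 2.52-fold higher level. Within replicate sets 1 and 2 they were 1.07 and 1.54 for macroH2A1 shRNA and 1.15 and 1.51 for macroH2A2 shRNA. The unadjusted limma p without the block was 7.38e-05 and 6.34e-05. Whether the published work picked Cdk8 from these same arrays was not examined. If it did, the unadjusted p is not an independent test, and only the adjusted p applies. Adjusted over all tested probe sets, the limma p was 0.222 and 0.428 without the block and 0.00835 and 0.0107 with it. Over 11 further settings of the blocked fit the adjusted p of Cdk8 was under 0.05 in 8 for macroH2A1 shRNA and in 10 for macroH2A2 shRNA, with ranges of 3.06e-05 to 0.110 and 0.000508 to 0.187 whose upper ends came without the filter. For macroH2A1 shRNA it was also 0.0513 without control shRNA replicate 2 and 0.0650 without macroH2A1 shRNA replicate 2. The difference between both lines was 0.03 (SE 0.17). The array measured Cdk8 with 1 probe set.

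**Figure D1:**
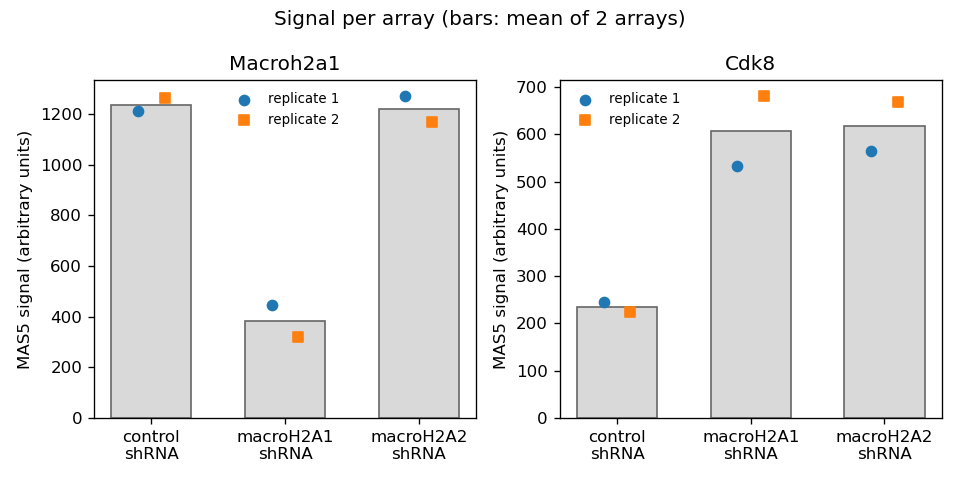
MAS5 signal in arbitrary units (vertical axes) of Macroh2a1 (left) and Cdk8 (right) in the 3 lines on the horizontal axes, with bars at the mean of 2 arrays, circles for replicate 1 and squares for replicate 2. The macroH2A1 shRNA arrays sit at 444.2 and 319.1 for Macroh2a1, below all other arrays, and the control arrays sit at 245.8 and 224.0 for Cdk8, below all other arrays.

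The comparison of macroH2A1 shRNA with control asked which transcripts differ once macroH2A1 is depleted. Besides Macroh2a1, the genes with the smallest p among those lower in the line, with no overlap between the 2 groups of arrays, were Cited1, a transcriptional coregulator, at 289.4 ± 11.03 against 1145 ± 250 (log2 fold change -1.91, SE 0.18), Oas1a, an interferon-induced synthetase, at 160.5 ± 30.3 against 526.0 ± 18.4 (-1.63, SE 0.17), Mndal, a member of the interferon-inducible p200 family (-2.23, SE 0.28), and Car8, a carbonic anhydrase-related protein (-1.32, SE 0.19). Those higher were Atp5g1, which encodes a subunit of mitochondrial ATP synthase, at 1282 ± 162 against 419.4 ± 87.9 (1.59, SE 0.18), Gpx4, which reduces lipid hydroperoxides (1.05, SE 0.13), Pacs2, a membrane sorting protein (1.30, SE 0.16), Cdk8, and Gnai2, an inhibitory G protein subunit (0.83, SE 0.12). A second probe set of Pacs2 did not share its direction (-0.04, SE 0.24).

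None of these genes passed the threshold without the block. With limma, 0 of 27025 tested probe sets had an adjusted p under 0.05 (smallest 0.123), and 1189 had an unadjusted p under 0.05 (570 higher and 619 lower), where chance gives 1351. With the replicate block 52 probe sets passed, 23 higher and 29 lower, among 2388 at an unadjusted p under 0.05, and the blocked adjusted p of the 10 genes named above lay between 0.00111 for Cited1 and 0.0177 for Gnai2. That count was 0 without the filter (smallest adjusted p 0.0807), 22 after quantile normalization, 24 with a 60th percentile filter and 32 with a pseudocount of 1. It was 34 without control shRNA replicate 1, 26 without macroH2A1 shRNA replicate 2, and 515 and 514 without macroH2A2 shRNA replicate 1 and 2. The 2 groups of arrays did not overlap for 7551 probe sets (27.9%), where chance gives 33.3%.

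Camera, a test of a gene list against the other genes, called 10 lists in macroH2A1 shRNA cells, 6 lower and 4 higher. Interferon-stimulated genes were lower. Of 30 tested members, 28 were lower, with a median log2 fold change of -0.64 (-0.77 and -0.53 in sets 1 and 2). Oas1a, Usp18, which removes the ubiquitin-like protein ISG15 (-1.80, SE 0.30), Xaf1 (-1.22, SE 0.21) and Rtp4 (-1.29, SE 0.24) had the smallest p. Adjusted over the list alone, 20 members fell and 0 rose, against 0 and 0 adjusted over all probe sets. With the block 23 fell over the list alone and 4 over all probe sets. The camera test called the list lower (adjusted p = 1.10e-24), and this call was lost with an estimated correlation (adjusted p = 0.284 with an estimated correlation). The 6 tested leukocyte markers had a median of 0.02, and the brightest of them in the control line, Csf1r, had a signal of 36.0.

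Antigen presentation genes were lower as well, 14 of 17 with a median of -0.52 (-0.71 and -0.21 within sets). They included Nlrc5, the transactivator of MHC class I genes (-0.95, SE 0.28), H2-D1 (-0.44, SE 0.16), H2-M3 (-0.58, SE 0.21) and Tap2, a subunit of the peptide transporter (-0.60, SE 0.24), and 0 changed when adjusted over the list alone, or 8 that fell with the block. The camera adjusted p was 1.44e-06 (adjusted p = 0.506 with an estimated correlation). Of 17 secreted inflammatory factors 11 were lower (median -0.17, -0.60 and -0.10 within sets), led by the chemokines Cxcl2 (-1.94, SE 0.33), Ccl20 (-1.78, SE 0.31), Cxcl1 (-1.37, SE 0.37) and Cxcl10 (-0.78, SE 0.23), and 4 fell adjusted over the list alone. The camera adjusted p was 0.000755 (adjusted p = 0.506 with an estimated correlation). PARP and NAD genes, 17 of 28 lower with a median of -0.11, had Parp12 (-0.67, SE 0.17), Parp9 (-0.72, SE 0.19), Macrod1 (-0.85, SE 0.23) and Parp3 (-0.97, SE 0.27) at their head and 0 members changed adjusted over the list alone, or 5 that fell with the block. Their camera adjusted p was 0.00592 (adjusted p = 0.506 with an estimated correlation), 0.118 without control shRNA replicate 2 and 0.0540 without macroH2A1 shRNA replicate 1. The interferon list shared 1 gene with the PARP list and 1 with the secreted factors. This counts listed symbols only, and whether the calls of these lists and of antigen presentation are separate from the interferon result was not tested.

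Hypoxia and glycolysis genes were lower in 24 of 32 cases, with a median of -0.24 (-0.43 in set 1, 0.0071 in set 2). Pfkp (-0.65, SE 0.20), Pfkfb3 (-0.67, SE 0.20), Slc2a1, a glucose transporter (-0.50, SE 0.18), and Egln3 (-0.78, SE 0.28) had the smallest p. Camera gave an adjusted p of 0.00114 (adjusted p = 0.841 with an estimated correlation), and the median turned to 0.10 without control shRNA replicate 1. In the control line all 32 members were higher on the replicate 1 array than on the replicate 2 array (median difference 0.52), as were 19 in the macroH2A1 shRNA line (0.07) and 6 in the macroH2A2 shRNA line (-0.27). Genes of the unfolded protein and amino acid stress response were lower in 31 of 38 cases (median -0.23, 0.02 and -0.44 within sets), with Slc7a11, the cystine transporter (-2.01, SE 0.51), Cebpb (-0.91, SE 0.37), Pdia4 (-0.34, SE 0.18) and Creld2 (-0.37, SE 0.20) first. Camera gave 0.00215 (adjusted p = 0.561 with an estimated correlation), and the adjusted p was 0.242 without control shRNA replicate 2 and 0.705 without macroH2A1 shRNA replicate 2. Adjusted over the list alone, 0 members of either list changed, and with the block 1 stress response gene fell.

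Lists that camera called higher in macroH2A1 shRNA cells were ribosomal proteins, oxidative phosphorylation, melanocyte differentiation and cholesterol synthesis, and quantile normalization ended all of these calls. Ribosomal protein genes were higher in 29 of 30 cases (median 0.24, with 0.19 and 0.31 within sets and 0.03 after quantile normalization), with Rps27 (1.32, SE 0.24) the member that rose when adjusted over the list alone, followed by Rps24 (0.27, SE 0.09), Rpl35 (0.29, SE 0.10) and Rpl10a (0.28, SE 0.09). With the block 21 rose and 1 fell by that adjustment. Camera gave 1.80e-17 (adjusted p = 0.284 with an estimated correlation) and 0.0999 after quantile normalization. Oxidative phosphorylation genes were higher in 49 of 52 cases (median 0.11, with 0.11 and 0.13 within sets), led by Atp5g1, the 1 member that rose adjusted over the list alone, Ndufa4 (0.34, SE 0.11), Ndufb7 (0.38, SE 0.13) and Cox5b (0.28, SE 0.11). Camera gave 2.59e-09 (adjusted p = 0.539 with an estimated correlation) and 0.209 after quantile normalization. Of 24 melanocyte genes 19 were higher (median 0.19, with 0.13 and 0.16 within sets), although 3 of the 4 with the smallest p were lower, namely Tyr, which encodes tyrosinase (-0.44, SE 0.13), Trpm1 (-0.69, SE 0.22) and Sox9 (-0.69, SE 0.25), while Oca2, a melanosomal transporter, was higher (0.54, SE 0.17). Camera gave 0.000931 (adjusted p = 0.539 with an estimated correlation) and 0.327 after quantile normalization, with 0 members changed over the list alone, or 2 that rose and 3 that fell with the block.

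Cholesterol synthesis genes were higher in 16 of 20 cases in macroH2A1 shRNA cells (median 0.13, but 0.37 in set 1 and -0.08 in set 2). Insig1 (0.42, SE 0.18), Tm7sf2 (0.45, SE 0.24), Fdft1 (0.28, SE 0.17) and Hmgcs1 (0.35, SE 0.24) had the smallest p, and 0 members changed adjusted over the list alone. Camera gave 0.0252 (adjusted p = 0.841 with an estimated correlation) and 0.0992 after quantile normalization. The median was -0.03 without control shRNA replicate 1, and the adjusted p was 0.532 without macroH2A1 shRNA replicate 1. With the block, camera also called heat shock genes higher (15 of 18, median 0.15, blocked adjusted p = 0.00876, and adjusted p = 0.819 with an estimated correlation) and integrins and adhesion genes lower (17 of 22, median -0.17, blocked adjusted p = 0.0228, and adjusted p = 0.819 with an estimated correlation). Without the block these lists had camera adjusted p values of 0.0593 and 0.0594. Hspa8 (0.34, SE 0.16) and Itga4, integrin alpha 4 (-1.03, SE 0.29), had the smallest p in them. Adjusted over the list alone, 0 members of either changed without the block, while with it 1 heat shock gene rose, and 1 adhesion gene rose and 2 fell. Itga4 also passed over all probe sets with the block (adjusted p 0.0440).

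The comparison of macroH2A2 shRNA with control asked the same of macroH2A2. Cited1 was lower (403.7 ± 51.7 against 1145 ± 250, log2 fold change -1.46, SE 0.18), as were Mndal (-1.84, SE 0.28), Sucnr1, the succinate receptor (-1.35, SE 0.21), Fam149a (-1.23, SE 0.20) and Acp1, a low molecular weight phosphatase, at 816.8 ± 79.0 against 1467 ± 25.1 (-0.84, SE 0.12). Atp5g1 was higher (1469 ± 186 against 419.4 ± 87.9, 1.78, SE 0.18), as were Pacs2 (1.56, SE 0.16), Cdk8, Nudt2, a hydrolase of dinucleoside polyphosphates (0.98, SE 0.14), and Gpx4 (0.83, SE 0.13). The second probe set of Pacs2 again read lower (-0.20, SE 0.24).

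With limma, 0 of 27025 probe sets passed in this comparison without the block (smallest adjusted p 0.150), and 1075 had an unadjusted p under 0.05, 393 higher and 682 lower. The share of higher ones was 36.6%, against 44.2% after quantile normalization and 49.8% with arrays centred on their median. With the block 39 probe sets passed, 16 higher and 23 lower, among 2426 at an unadjusted p under 0.05, and the blocked adjusted p of the 10 named genes lay between 0.00588 and 0.0306. The blocked count was 0 without the filter (smallest adjusted p 0.129) and 16 after quantile normalization. It was 3 without control shRNA replicate 1, 96 without control shRNA replicate 2, 138 and 133 without macroH2A1 shRNA replicate 1 and 2, and 114 and 804 without macroH2A2 shRNA replicate 1 and 2. For 7880 probe sets (29.2%, chance 33.3%) the 2 groups of arrays did not overlap.

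Camera called 9 lists in macroH2A2 shRNA cells, 5 lower and 4 higher, or 17 without macroH2A2 shRNA replicate 2. Interferon-stimulated genes were lower in 28 of 30 cases, with a median of -0.62 (-0.72 and -0.45 within sets). Oas1a (-1.06, SE 0.17), Xaf1 (-1.26, SE 0.21), Rtp4 (-1.36, SE 0.24) and Bst2, the virion tether (-0.75, SE 0.14), came first, and 16 members fell adjusted over the list alone, against 0 over all probe sets. With the block these counts were 21 and 4. Camera gave 6.64e-20 (adjusted p = 0.654 with an estimated correlation). Leukocyte markers had a median of -0.17. Antigen presentation genes were lower in 14 of 17 cases (median -0.40, -0.75 and -0.20 within sets), with Nlrc5 (-1.28, SE 0.28), H2-M3 (-0.80, SE 0.21), Tap1 (-0.83, SE 0.22) and H2-D1 (-0.53, SE 0.16), and 4 fell adjusted over the list alone, or 8 with the block. Camera gave 3.83e-07 (adjusted p = 0.654 with an estimated correlation). Secreted inflammatory factors were lower in 13 of 17 cases (median -0.15, -0.34 and -0.09 within sets), led by Cxcl2 (-1.69, SE 0.33), Ccl20 (-1.54, SE 0.31), Cxcl10 (-0.71, SE 0.23) and Cxcl1 (-1.05, SE 0.37), and 2 fell adjusted over the list alone, or 4 with the block. Camera gave 0.000794 (adjusted p = 0.654 with an estimated correlation).

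**Figure D2:**
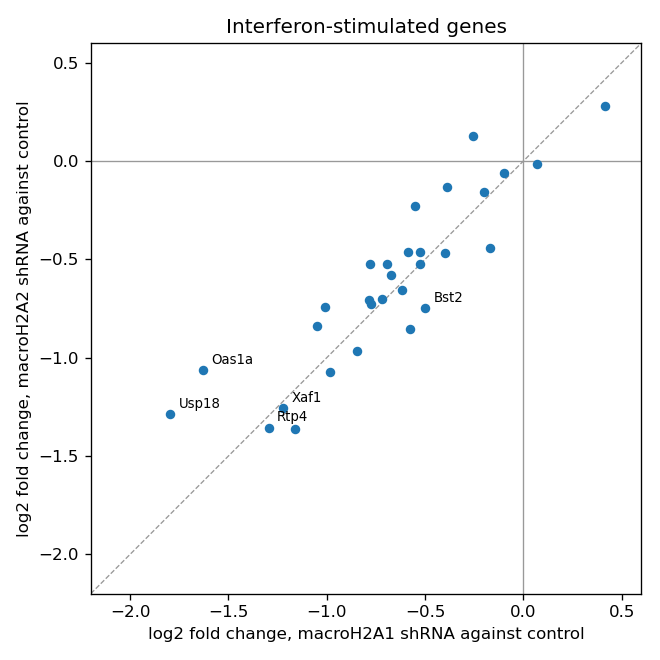
Log2 fold change of 30 interferon-stimulated genes in the macroH2A1 shRNA line (horizontal axis) and the macroH2A2 shRNA line (vertical axis), each against the same control arrays, 1 point per gene, with a dashed line of equality and 5 genes named. In each line 28 of the 30 genes lie below 0, with medians of -0.64 and -0.62.

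Hypoxia and glycolysis genes were lower in 31 of 32 cases in macroH2A2 shRNA cells (median -0.45, -0.70 in set 1 and 0.03 in set 2). Slc2a1 (-0.80, SE 0.18), Egln3 (-0.99, SE 0.28), Pfkp (-0.65, SE 0.20) and Car9, a carbonic anhydrase (-0.66, SE 0.22), came first, with 0 changed over the list alone, or 10 that fell with the block. Camera gave 6.66e-12 (adjusted p = 0.675 with an estimated correlation). Stress response genes were lower in 30 of 38 cases (median -0.17, -0.29 in set 1 and 0.19 in set 2), with Slc7a11 (-1.70, SE 0.51), Cebpb (-0.86, SE 0.37), Dnajc3 (-0.28, SE 0.15) and Creld2 (-0.31, SE 0.20). Camera gave 0.0279 (adjusted p = 0.705 with an estimated correlation). Its adjusted p was 0.666 without control shRNA replicate 2, and its median was 0.12 without macroH2A2 shRNA replicate 1, while 0 members changed adjusted over the list alone.

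Oxidative phosphorylation genes were higher in 49 of 52 cases in macroH2A2 shRNA cells (median 0.11, with 0.16 and 0.07 within sets), with Atp5g1 rising adjusted over the list alone and Ndufb2 (0.29, SE 0.14), Ndufa2 (0.22, SE 0.11) and Ndufb7 (0.24, SE 0.13) after it. Camera gave 3.08e-07 (adjusted p = 0.675 with an estimated correlation) and 0.0853 after quantile normalization. Ribosomal protein genes were higher in 27 of 30 cases (median 0.08, with 0.08 and 0.12 within sets), with Rps27 (1.29, SE 0.24) rising adjusted over the list alone and Rps9 (0.24, SE 0.12), Rps3 (0.14, SE 0.10) and Rpl8 (0.13, SE 0.10) next. Camera gave 0.000368 (adjusted p = 0.654 with an estimated correlation) and 0.698 after quantile normalization. Heat shock genes were higher in 16 of 18 cases (median 0.23, with 0.35 and 0.05 within sets), with Ahsa1 (0.36, SE 0.18), Cryab (0.29, SE 0.16), Dnaja1 (0.40, SE 0.22) and Hspd1 (0.24, SE 0.16), at a camera adjusted p of 0.000794 (adjusted p = 0.705 with an estimated correlation), or 0.634 without control shRNA replicate 1. Cholesterol synthesis genes were higher in 15 of 20 cases (median 0.15, 0.36 in set 1 and -0.04 in set 2), with Insig1 (0.39, SE 0.18), Lss (0.31, SE 0.19), Nsdhl (0.24, SE 0.15) and Dhcr7 (0.34, SE 0.23), at 0.0163 (adjusted p = 0.705 with an estimated correlation) and 0.0712 after quantile normalization. Without control shRNA replicate 1 the direction of that test turned (median 0.01), and without macroH2A2 shRNA replicate 1 its adjusted p was 0.642. With the block, core histone genes were called lower (6 of 8, median -0.29, blocked adjusted p = 0.0152, and adjusted p = 0.645 with an estimated correlation), with H2bc21 (-0.69, SE 0.26) first, against 0.0806 without the block. Adjusted over the list alone, 0 members of the heat shock, cholesterol synthesis and core histone lists changed, and with the block 1 core histone gene fell.

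Camera did not call the other lists in either line. Median log2 fold changes in macroH2A1 and macroH2A2 shRNA cells were 0.05 and -0.11 for CDK inhibitors and p53 targets, 0.09 and 0.04 for G1/S and DNA replication, -0.05 and -0.0030 for G2/M and mitosis, -0.03 and -0.06 for MAP kinase feedback and immediate early genes, and 0.01 and 0.01 for beta-catenin and TCF targets. They were -0.0033 and 0.0090 for chromatin regulators, -0.06 and 0.0011 for homeobox and other Polycomb target factors, -0.04 and -0.15 for imprinted genes, 0.03 and -0.05 for lysosome and autophagy genes, and -0.14 and -0.05 for matrix, invasion and mesenchymal genes. Fibroblast markers had medians of -0.03 and -0.28, the Mediator kinase module -0.01 and 0.03, and the macroH2A and H2A variant genes 0.10 and 0.06. Core histone genes had a median of -0.20 in macroH2A1 shRNA cells, while integrins had -0.12, melanocyte genes 0.07 and PARP and NAD genes -0.14 in macroH2A2 shRNA cells. Keratinocyte and endothelial markers had too few tested members for a test (4 and 2). The sign of the median differed from that of the mean or the test for the Mediator kinase module, the variant genes, beta-catenin targets, chromatin regulators and leukocyte markers in macroH2A1 shRNA cells. It differed for G2/M, chromatin regulators, homeobox factors and the variant genes in macroH2A2 shRNA cells. Adjusted over the list alone, Cdk8 and its module partner Med12l (0.71, SE 0.20) rose in macroH2A1 shRNA cells, Cdk8 rose in macroH2A2 shRNA cells, and Macroh2a1 and H2ax (-0.62, SE 0.16) fell in macroH2A1 shRNA cells. For Cdk8 this adjustment over a short list carries the same reservation as its unadjusted p. By the same adjustment Zmat3 (0.87, SE 0.17) and Atp6v0d1 (0.56, SE 0.13) rose and Ctsh (-0.97, SE 0.21) fell in macroH2A1 shRNA cells, Pdgfra fell in both lines (-0.89, SE 0.25 and -0.99, SE 0.25), and 0 members of the remaining uncalled lists changed without the block. With the block the same adjustment gave, in macroH2A2 shRNA cells, 3 higher and 2 lower members for MAP kinase feedback, 1 and 3 for matrix genes, 1 and 2 for lysosome and autophagy genes, 0 and 4 for PARP and NAD genes, 2 and 0 for the Mediator kinase module, and 0 and 1 for imprinted genes and for integrins. In macroH2A1 shRNA cells it gave 2 higher CDK inhibitors and p53 targets and 1 lower imprinted gene, and the other counts stayed as they were.

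What both macroH2A shRNA lines shared against the control was tested with the mean of both. Atp5g1 (1.68, SE 0.16), Pacs2 (1.43, SE 0.14), Cdk8 (1.32, SE 0.15), Gpx4 (0.94, SE 0.11) and Gnai2 (0.78, SE 0.10) were higher. Cited1 (-1.68, SE 0.16), Oas1a (-1.35, SE 0.15), Mndal (-2.04, SE 0.25), Car8 (-1.16, SE 0.17) and Xaf1 (-1.24, SE 0.18) were lower. With limma, 0 probe sets passed without the block (smallest adjusted p 0.0619) and 1217 had an unadjusted p under 0.05, 544 higher and 673 lower, or 44.7% higher against 56.2% with arrays centred on their median. At an adjusted p under 0.10 the count was 3, namely Atp5g1, Pacs2 and Cited1. With the block 84 probe sets passed, 34 higher and 50 lower, among 2631 at an unadjusted p under 0.05. That count was 0 without the filter (smallest adjusted p 0.0567) and 46 after quantile normalization, and 19 without control shRNA replicate 1, 152 without macroH2A1 shRNA replicate 1, and 288 and 867 without macroH2A2 shRNA replicate 1 and 2. For 3439 probe sets (12.7%, chance 13.3%) the control arrays did not overlap the other 4.

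Among the gene lists, camera called 11 for the mean of both lines, 5 higher and 6 lower, and 0 with an estimated correlation (adjusted p = 0.411 to 0.675 with an estimated correlation). The camera adjusted p of these 11 lists lay between 1.62e-25 and 0.0220. Interferon-stimulated genes had a median of -0.63, with 21 members that fell adjusted over the list alone, and with the block 22 over the list alone and 7 over all probe sets. Antigen presentation genes had -0.41 with 5 that fell, hypoxia and glycolysis genes -0.40 (-0.73 in set 1 and 0.049 in set 2) with 0, stress response genes -0.20 with 0, PARP and NAD genes -0.14 with 4 and secreted inflammatory factors -0.07 with 4. With the block these counts were 8 for antigen presentation, 8 for hypoxia, 1 for the stress response, 5 for PARP and NAD genes and 4 for secreted factors. Medians of the higher lists were 0.17 for ribosomal proteins, 0.12 for oxidative phosphorylation, 0.18 for heat shock genes, 0.15 for melanocyte genes and 0.16 for cholesterol synthesis (0.34 in set 1 and -0.11 in set 2). After quantile normalization 5 lists were called, all with a lower median, since the call of each higher list ended (adjusted p 0.0502 to 0.501), as did that of PARP and NAD genes (0.0502). Without control shRNA replicate 1 the count was 7, with medians of 0.0019 for cholesterol synthesis and -0.02 for heat shock genes, and with adjusted p values of 0.427 for hypoxia and 0.106 for melanocyte genes. Without control shRNA replicate 2 the adjusted p was 0.293 for PARP and NAD genes and 0.432 for the stress response. Without macroH2A1 shRNA replicate 1 it was 0.0941 for cholesterol synthesis, and without replicate 2 of that line 0.0987 for heat shock genes and 0.0548 for the stress response. Without macroH2A2 shRNA replicate 1 it was 0.122 for PARP and NAD genes, 0.157 for cholesterol synthesis and 0.320 for the stress response, and without replicate 2 of that line 0.0556 for melanocyte genes. With the block the count was 13, as core histone genes (median -0.21, blocked adjusted p = 0.0172, and adjusted p = 0.523 with an estimated correlation) and integrins (median -0.18, blocked adjusted p = 0.0208, and adjusted p = 0.833 with an estimated correlation) were added, of which 3 core histone genes and 2 integrin genes fell adjusted over the list alone with the block, against 0 and 0 without it. The sign of the median differed from that of the mean or the test for CDK inhibitors and p53 targets, the Mediator kinase module, chromatin regulators and the variant genes.

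Fold changes of both lines correlated across the 27025 probe sets with r = 0.595, where probe sets are not independent replicates. Both lines were set against the same control arrays, and simulated unchanged groups with those controls gave r = 0.498. The covariance was 0.0363, against a simulated 0.0449 with the spread of the fit without the block and 0.0231 with the spread of the blocked fit. The difference was therefore below 0 in one case (-0.0085) and above 0 in the other (0.0132). Signs matched for 70.2% of probe sets, against 66.7% in the simulation. Within sets 1 and 2 the correlation was 0.610 and 0.482, and it was 0.344 without macroH2A1 shRNA replicate 2. The last value has no simulated counterpart, because leaving out an array changes the correlation that shared controls alone give. Of the blocked calls, 11 higher and 9 lower probe sets were shared by both lines. Both sets of calls rest on the same control arrays, which cannot be split with at least 2 arrays on each side, so this overlap was not set against chance.

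The direct comparison of macroH2A2 with macroH2A1 shRNA cells tested where the lines differ. Macroh2a1 was higher in macroH2A2 shRNA cells (log2 fold change 1.65, SE 0.17), with a blocked adjusted p of 0.00545 and 0.309 without the block. Septin11, a cytoskeletal GTPase (0.92, SE 0.15), Pmp22, a myelin membrane protein (0.76, SE 0.13), Ube2j2 (0.75, SE 0.14) and Apip (0.94, SE 0.18) were also higher, and Dcdc2a (-1.26, SE 0.19), Acp1 (-0.80, SE 0.12), Nop10, a small nucleolar RNA-binding protein (-0.81, SE 0.13), Tcf7l1, a TCF transcription factor (-1.003, SE 0.17), and Limd2 (-0.89, SE 0.15) were lower. These 9 genes had blocked adjusted p values between 0.135 and 0.183, and a second probe set of Ube2j2 read lower (-0.12, SE 0.34). With limma, 0 of 27025 probe sets passed without the block (smallest adjusted p 0.309), 739 had an unadjusted p under 0.05, and Macroh2a1 was the 1 probe set that passed with it, among 1711 at an unadjusted p under 0.05. The 2 groups of arrays did not overlap for 7564 probe sets (28.0%, chance 33.3%).

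Camera called 3 lists lower in macroH2A2 than in macroH2A1 shRNA cells. Ribosomal protein genes were lower in 28 of 30 cases (median -0.15, with -0.12 and -0.15 within sets), with Rpl22 (-0.24, SE 0.09) first, at 1.35e-07 (adjusted p = 0.919 with an estimated correlation) and 0.357 after quantile normalization. Hypoxia and glycolysis genes were lower in 27 of 32 cases (median -0.21, with -0.33 and -0.0039 within sets), with Pfkl (-0.61, SE 0.26) first, at 0.000115 (adjusted p = 0.927 with an estimated correlation), or 0.523 without macroH2A2 shRNA replicate 1. CDK inhibitors and p53 targets were lower in 13 of 22 cases (median -0.19, with -0.11 and -0.18 within sets), with the p53 targets Zmat3 (-0.72, SE 0.17), Trp53inp1 (-0.75, SE 0.21), Cdkn1a, the CDK inhibitor p21 (-0.64, SE 0.29), and Plk2 (-0.74, SE 0.34), at 0.00238 (adjusted p = 0.919 with an estimated correlation). That adjusted p was 0.137 without macroH2A1 shRNA replicate 2 and 0.0966 without macroH2A2 shRNA replicate 1. The number of called lists was 9 and 5 without macroH2A1 shRNA replicate 1 and 2, and 7 and 9 without macroH2A2 shRNA replicate 1 and 2. Over the 3 lists, 0 members changed adjusted over the list alone, or, with the block, 3 CDK inhibitors and p53 targets that fell. Interferon-stimulated genes differed between the lines by a median of 0.04, with a camera adjusted p of 0.306. The sign of the median differed from that of the mean or the test for MAP kinase feedback, cholesterol synthesis, the variant genes, matrix genes and secreted factors.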

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

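All tests of these lists were planned. Camera on the difference between the macroH2A shRNA lines, macroH2A2 minus macroH2A1, drew attention to 3 gene lists whose effects differed between the lines. CDK inhibitors and p53 targets differed by a median log2 value of -0.19 (-0.11 and -0.18 within replicate sets 1 and 2), at a camera adjusted p of 0.00238 (adjusted p = 0.919 with an estimated correlation), or 0.137 without macroH2A1 shRNA replicate 2 and 0.0966 without macroH2A2 shRNA replicate 1. Hypoxia and glycolysis genes differed by -0.21 (-0.33 and -0.0039 within sets), at a camera adjusted p of 0.000115 (adjusted p = 0.927 with an estimated correlation), or 0.523 without macroH2A2 shRNA replicate 1. Ribosomal protein genes differed by -0.15 (-0.12 and -0.15 within sets), at a camera adjusted p of 1.35e-07 (adjusted p = 0.919 with an estimated correlation), and this call ended after quantile normalization, at -0.03 (adjusted p = 0.357).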

How the results depend on the processing

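The settings of the blocked fit were chosen after the results were seen, and the other tests here were planned, except centring, a pseudocount of 1 and the block with an estimated correlation for gene lists. The replicate block moved the counts of probe sets past the threshold from 0 to 52 for macroH2A1 shRNA, 39 for macroH2A2 shRNA, 84 for the mean of both lines and 1 between the lines. It brought past the threshold 47 values of named genes. Among them were the log2 fold changes of Macroh2a1 in macroH2A1 shRNA cells, -1.67, and of Cdk8 in both lines, 1.30 and 1.33. It added the list calls given with the comparisons and ended 0. Adjusted over the list alone it also changed member counts, for ribosomal proteins in macroH2A1 shRNA cells from 1 to 21 that rose, and for hypoxia and glycolysis in macroH2A2 shRNA cells from 0 to 10 that fell. At an adjusted p under 0.10 the mean of both lines had 3 probe sets. The 2546 other values of named genes kept their direction and side of the threshold. Since 0 of these genes passed without the block, an unchanged side means only that the value still did not pass. Choosing genes by small p or non-overlapping groups also favours a kept direction.

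With an estimated correlation between genes, 0 lists passed for macroH2A1 shRNA, 0 for macroH2A2 shRNA, 0 for the mean of both lines and 0 between the lines, and the same counts, 0, 0, 0 and 0, came from the replicate block with an estimated correlation. Quantile normalization left 5 lists for the mean of both lines and ended 14 list calls, while centring the arrays, another pseudocount and the mean of a gene's probe sets ended 0. Of the list values, 354 kept direction and call, 102 lost the call and 6 reversed. The cause was not tested.

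With the replicate block, the counts for macroH2A1 shRNA were 32 with a pseudocount of 1, 22 after quantile normalization, 0 without the filter and 24 with the 60th percentile filter. For macroH2A2 shRNA they were 16 after quantile normalization and 0 without the filter, and for the mean of both lines 46 and 0. Without the filter the blocked limma adjusted p of Macroh2a1 in macroH2A1 shRNA cells went from 0.00120 to 0.0807. The added number of probe sets alone cannot give so large a rise. In that fit the variance trend and prior were also estimated with the dim probe sets, so the blocked calls depend on the variance model. Leaving out 1 array in turn, the blocked counts ranged from 26 to 515 for macroH2A1 shRNA, from 3 to 804 for macroH2A2 shRNA and from 19 to 867 for the mean of both lines. Such a fit keeps 1 residual degree of freedom, and the lone array of a line is taken to vary like the others.

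Leaving out 1 array in turn, the correlation of fold changes between the lines ranged from 0.344 (without macroH2A1 shRNA replicate 2) to 0.817 (without control shRNA replicate 2). The correlation that shared controls alone give also changes with the arrays left, and it was simulated for the full set only. This range therefore does not measure how stable a shared effect is. The number of lists called ranged from 8 to 17 for macroH2A2 shRNA, from 7 to 13 for the mean of both lines and from 3 to 9 between the lines. Median log2 values ranged from -0.031 to 0.30 for cholesterol synthesis and from -0.48 to 0.10 for hypoxia and glycolysis in macroH2A1 shRNA cells. They ranged from 0.011 to 0.25 for cholesterol synthesis and from -0.39 to 0.12 for the stress response in macroH2A2 shRNA cells, and from 0.0019 to 0.29 for cholesterol synthesis and from -0.020 to 0.33 for heat shock genes in the mean of both lines. Signal over background limits dim transcripts, since the filter lay at 10.4 signal units and Macroh2a2 read between 2.0 and 11.9.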

Other observations

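The tests of explanations for the interferon list, camera with the block and an estimated correlation, and the test of the probe set of Cdk8 were chosen only after the result was seen, and the genes of the next paragraph were picked after their values were seen. The neighbours of Cdk8 and the correlation over disjoint arrays were tests written before their results.

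Several genes not described so far passed with the replicate block. Washc5, a subunit of the endosomal WASH complex, was higher in macroH2A1 and macroH2A2 shRNA cells by 1.30 (SE 0.21) and 1.21 (SE 0.21) on the log2 scale, and Ripor2 by 1.44 (SE 0.26) and 1.12 (SE 0.26). In macroH2A1 shRNA cells Nrp2, which encodes the receptor neuropilin 2, was lower on both called probe sets (-0.96, SE 0.21, and -1.14, SE 0.24), and in macroH2A2 shRNA cells Hmga2, an architectural chromatin protein, was lower (-1.21, SE 0.20). Malat1, a nuclear long noncoding RNA, was lower in macroH2A2 shRNA cells on 3 probe sets (-1.36, -1.37 and -1.08), with standard errors of 1.06, 1.11 and 0.96 without the block. On each of these probe sets the 2 groups of arrays overlapped. On the first, the mean signal ± SD was 1390 ± 1420 in the control line, 769.5 ± 753 in the macroH2A1 shRNA line and 493.9 ± 477 in the macroH2A2 shRNA line. All log2 fold changes of this paragraph had a blocked limma adjusted p under 0.05 and none had one without the block.

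Camera with a preset correlation called interferon-stimulated genes lower in both macroH2A shRNA lines. This call was lost with an estimated correlation, at adjusted p values of 0.284 for macroH2A1 shRNA, 0.654 for macroH2A2 shRNA and 0.411 for the mean of both, or 0.540, 0.645 and 0.523 with the block as well. RNA of leukocytes in the control cultures is argued against as the source, since it would bring their abundant transcripts. The 13 markers on the array were lower in the macroH2A shRNA arrays than in the control arrays by a median of 1.38 signal units (SE 1.26), against 60.1 (SE 37.4) for the 30 list members, 27 of which had a larger signal difference than any marker. Signal differences also depend on the probe sets, and 6 of the 13 markers passed the filter. The argument therefore holds only as far as these probe sets detect leukocyte RNA. A single deviant control array is argued against as well, since the median was -0.48 (SE 0.09, 26 of 30 lower) in the replicate set where it was smaller and -0.71 (SE 0.12) in the other. The SEs of this paragraph are over genes read on the same arrays, which are not independent. They do not measure variation between arrays or cultures. The argument therefore rests on a lower median in both sets, each with 1 array per line. The median difference between the lines was 0.043, so a level particular to the control line cannot be told apart from an effect of losing macroH2A, because 1 control line carries the comparison. Another hairpin was not tested.

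Cdk8 was higher in both macroH2A shRNA lines. A copy number difference of a segment spanning most of its 20 nearest measured genes is argued against. These genes had a median log2 fold change of 0.068 (SE over genes 0.045, from -0.15 to 0.52), against 1.32 for Cdk8. A gain limited to Cdk8 or to few neighbours would leave this median near 0, so the test cannot decide on it. Cross-hybridisation or another fault of the probe set cannot be told apart from a change in the transcript, because the array held 1 probe set for the gene. A level particular to the control line also stays open, so on these arrays alone higher Cdk8 upon loss of macroH2A remains a hypothesis. Other experiments of the published work on Cdk8 were not examined here.

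Fold changes of the lines were correlated across probe sets. The shared control arrays alone are argued against as the cause, since with each line set against a different control array the correlation was 0.14 and 0.15 in the 2 ways of choosing arrays, across 27025 probe sets that are not independent. After quantile normalization, a setting chosen after the result was seen, the values were 0.15 and 0.14. A level particular to the control line, present on both control arrays, may still account for this correlation, as may a shared effect of both hairpins. Subtraction within a set also leaves any replicate set effect of unequal size in the lines. On the first principal component the control array lay lowest in set 1 (-45.1 against -26.4 and -11.5). It also lay lowest in set 2 (21.9 against 32.8 and 28.2). How much of the correlation this gives was not tested.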
